A study of Homo sapiens with 10 samples.

How the data were processed

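Expression was measured on 10 whole-transcript oligonucleotide arrays, 1 per RNA sample, in HEK293 cells, an established line made from human embryonic kidney. Per the labels, 3 samples were untreated cells, 3 were cells stably carrying a MAML1 expression plasmid, 2 were cells given a non-targeting siRNA and 2 were cells given a pool of 4 siRNAs against MAML1. Per the labels' protocols, siRNAs were used at 100 nM, cells were collected 72 h later, stable clones were selected with geneticin, and 200 ng of RNA was labelled for each array. The labels give no scan date or other batch.

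Per the file headers, the authors processed the arrays with Expression Console by RMA: background correction, quantile normalisation over all probes and median polish gave 1 log2 value per transcript cluster (the set of probes for 1 transcript locus). The deposited log2 values ran from 1.54 to 14.08 and were rounded to 2 decimals. The release of Expression Console was not given in the sources used here. Per the file headers, the annotation was NetAffx build 31 on the hg19 genome build, and the authors took log2 5 as the background cutoff. The same deposited table held the authors' group mean signal on the linear scale and the authors' signed fold change per transcript cluster, a score in which a negative sign marks a lower first group. It also held the authors' p-value and q-value for the overexpression and knockdown comparisons, with no test named. When recomputed here, an equal-variance t-test on linear values gave 100% of the overexpression p-values and 99.97% of the knockdown p-values to within 1 percent. A second deposited table of log2 values was identical, with a largest difference of 0.

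The table had 33297 transcript clusters, of which 26890 were of the main category and the others were controls or had no place in the main design. Of the main clusters, 22371 had 1 gene symbol and 4519 had none. Symbols were brought up to date through the Entrez ID, then the symbol, then synonyms, in the RefSeq gene table of assembly GRCh38.p14. That gene table also served to keep only protein-coding members in the ribosomal, zinc finger and oxidative phosphorylation lists. By this route 19933 genes were named through the Entrez ID and 339 kept the file's symbol. Where a gene had more than 1 cluster, as 1393 genes did, the cluster with the highest mean over all arrays stood for it, which gave 20324 genes. No filter on dim genes was used. Coordinates and gene order are from the hg19 positions of the deposited table. Probe sets that cross-hybridise, per the deposited annotation, stood for 1211 of the genes.

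All 10 arrays entered 1 fit of the 4 group means with lmFit and eBayes of limma 3.58.1 in R 4.3.3. Changed genes were those with a Benjamini-Hochberg adjusted p below 0.05. The series text gives a filter of p below 0.01 and a change of at least 1.5-fold without saying whether p was adjusted, so it was read as unadjusted. Contrasts were overexpression against untreated, siMAML1 against siControl, siControl against untreated, and the overexpression effect minus the knockdown effect. All adjusted p-values of single genes are from limma, and errors of log2 changes are standard errors of that fit. Group levels carry the SD over their arrays. Where 1 group of a gene lay below log2 5, the fold is given as at least the other group's level over that cutoff. Since 3 arrays against 3 cannot give an exact 2-sided permutation p under 0.1, no permutation test of single genes was run.

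Of the 36 gene lists fixed before the data were examined, 35 had members on the array and were tested with camera of limma at a preset correlation of 0.01, with camera's estimated correlation, and with fry, which tests whether a list's genes move, on balance, one way. Their p-values were adjusted over the lists within each comparison. The 1 remaining list, of mitochondrially encoded genes, had 0 members on the array. A list member counted as having risen or fallen if it passed over all genes, and the count adjusted over the list alone is given beside it. Some genes were in more than 1 list and were counted in each, so the lists are not independent. The comparisons, tests, lists, alternative settings and the rule for named genes were likewise chosen before the data were examined. The rule named MAML1, the 12 genes with the largest rise and the 12 with the largest fall with overexpression, 6 of each in the other 2 comparisons, and up to 4 members of each described list with the smallest p. It took only genes past the adjusted p whose arrays did not overlap between the groups, and where fewer passed it took the smallest p instead. Uncharacterised symbols were skipped, and 1 gene that the rule named is not reported here.

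Array quality was checked on the median, the spread of deviations from each gene's median over all arrays and the control features. Chromosome medians used genes with a mean above log2 7 and were set against 10000 random sets matched on mean expression. Calls of neighbouring genes were set against 10000 shuffles within chromosome arm and 5 classes of expression. Counts were repeated over the 10 ways of parting the 6 untreated and overexpressing arrays into 3 and 3. The covariance and opposite signs between comparisons with shared controls were set against 100 simulated sets of arrays without effects. Alternatives were quantile normalisation of the genes, centring of each array, removal of the dimmest 40% of genes, a trended robust fit, a fit of the compared groups only, array quality weights, the mean over all clusters of a gene, each transcript cluster by itself, the second deposited table, stricter thresholds, a block for the replicate number, a plain t-test and leaving out each array. Added after the data were seen were a t-test on linear values, the series filter with a group mean of at least log2 5, fits without siMAML1 replicate 1 and fits without chromosomes 18, 20 and 16q. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.

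The fit was tested on simulated data of 20324 genes. For overexpression against untreated, 71% of genes changed 1.5-fold and 97% of genes changed 2-fold were recovered, with 15 false calls. For siMAML1 against siControl, the shares were 59% and 89%, with 7 false calls. In a simulated overexpression comparison with a shift of 0.3 placed in 1 list, camera called that list and 0 others. The simulated genes varied independently, so this does not show how often camera calls lists wrongly in real arrays. There, a wrong parting of the 6 untreated and overexpressing arrays gave up to 6 called lists. The number of arrays limits the precision, since a group had 2 or 3. Background control features had a median of log2 3.34, and 6115 genes (30.1%) had a mean below log2 5.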

Results

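Gene expression was measured in HEK293 cells with more or with less MAML1, a transcriptional coactivator that joins the Notch intracellular domain and its DNA-binding partner and recruits the histone acetyltransferase p300. The 10 arrays fell into 4 groups. Untreated cells and cells stably overexpressing MAML1 had 3 arrays each. Cells given a non-targeting siRNA (siControl) and cells given siRNAs against MAML1 (siMAML1) had 2 each, collected 72 h after transfection. The series asked which genes respond when MAML1 is raised or lowered, with attention to DNA methylation and to developmental gene clusters. No cells carrying an empty vector were among the samples, so the overexpressing cells, selected with geneticin, were compared with untreated parental cells. For every gene in that comparison, effects of MAML1, of selection and of the clone cannot be told apart. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples. Values are log2 expression for 20324 genes, and within every group the correlation between arrays across genes was 0.997 to 0.998. On siMAML1 replicate 1, the median gene lay at 6.97, against 7.02 to 7.11 on the other arrays.

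MAML1 itself was higher in the overexpressing cells and lower on both siMAML1 arrays. Its transcript cluster lies on chromosome 5 at 179159851 to 179223512 (hg19) and has 56 probes. Its log2 level was 6.80 ± 0.07 (SD, n = 3) in untreated cells and 7.38 ± 0.12 (n = 3) with overexpression. This was a rise of 0.58 ± 0.11 (SE), with a limma adjusted p of 0.0199. Without untreated replicate 1, 2 or 3 or without overexpression replicate 3, that adjusted p was 0.0514, 0.0779, 0.0687 or 0.0695, with a change of 0.51 to 0.62 over all arrays left out. In the authors' deposited values MAML1 rose 1.4975-fold with a q-value of 0.0903, just short of the 1.5-fold of the series filter. Which of its probes match the plasmid was not examined. After siRNA, MAML1 was at 6.85 on average in the siControl arrays and 6.33 in the siMAML1 arrays, a difference of -0.52 ± 0.14 that did not pass (limma adjusted p = 0.174). The siMAML1 arrays read 6.10 and 6.56 and the siControl arrays 6.87 and 6.83. Without siMAML1 replicate 1 the difference was -0.29, and without replicate 2 it was -0.75. The overexpression and knockdown effects on MAML1 differed from each other (limma adjusted p = 0.0155). The siControl cells did not differ detectably from untreated cells in MAML1 (0.05, limma adjusted p = 0.835).

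**Figure D1:**
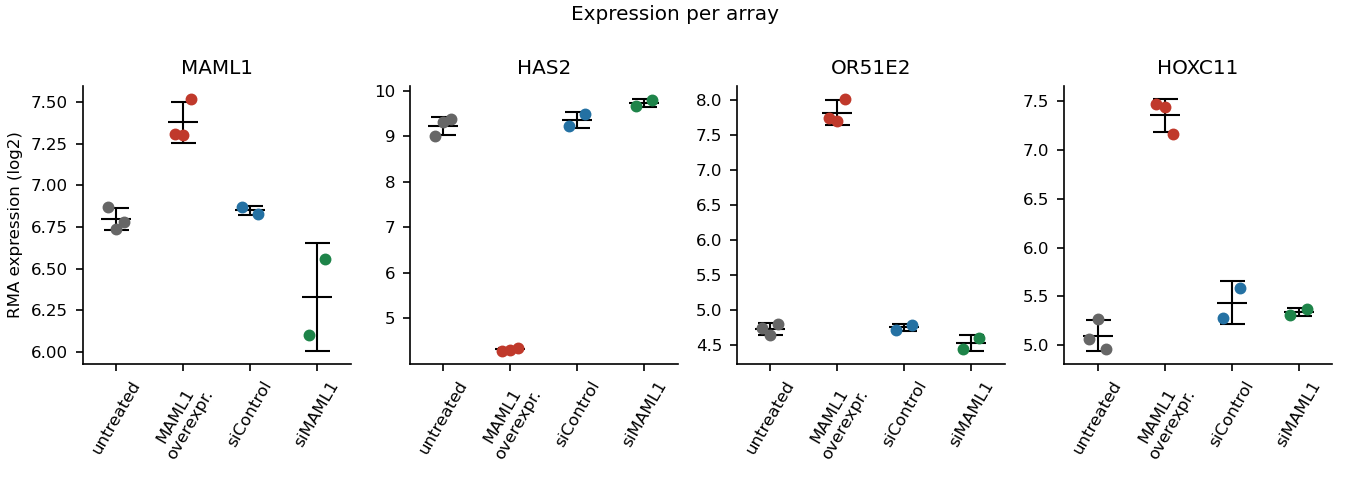
Log2 expression of MAML1, HAS2, OR51E2 and HOXC11 on each array, by group; points are arrays, and black lines are the group mean ± SD. HAS2 lay at 9.23 in untreated and 4.32 in overexpressing cells, while OR51E2 and HOXC11 were higher in all 3 overexpressing arrays than in any other array.

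The first comparison asked what raised MAML1 does to expression, with overexpressing against untreated cells. HAS2, which makes the matrix polysaccharide hyaluronan, went from 9.23 ± 0.20 to 4.32 ± 0.04 (SD, n = 3 and 3), a fall of at least 18.8-fold, counted against the background cutoff of log2 5 since the lower level lay below it. OR51E2, an olfactory receptor also expressed outside the nose, rose from 4.72, below the cutoff, to 7.82, or at least 7.06-fold. HOXC11, a homeobox gene of the posterior HOXC cluster, rose 4.79-fold from 5.10 to 7.36. In all, 1024 genes changed, 462 up and 562 down, and 254 of them changed at least 1.5-fold, 98 up and 156 down.

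The measured differences of OR51E2 (3.10 ± 0.09) and HOXC11 (2.26 ± 0.12) had limma adjusted p-values of 3.69e-07 and 9.82e-06. Of the 24 genes with the largest measured differences, 13 had 1 group below the cutoff and AADACL4 had both, so the order of these sizes is not settled. TNMD, which encodes the tendon protein tenomodulin, rose from 3.98, below the cutoff, to 6.46 (at least 2.75-fold, adjusted p = 6.43e-05). OSTN, which encodes the secreted peptide osteocrin, rose by 2.13 ± 0.18 (adjusted p = 0.000197). ITGA8, an integrin subunit needed in kidney development, rose from 7.82 to 9.38, and ACVR1C, a receptor for activin-like ligands, rose by 1.50 ± 0.08. Genes for hair keratin-associated proteins on chromosome 21 also rose: KRTAP19-5 by 1.81, KRTAP19-1 by 1.64 and KRTAP19-3 at least 1.58-fold, all between positions 31852299 and 31874435. ASB11, a subunit of ubiquitin ligases, went from 3.26, below the cutoff, to 5.06. LY6G6D has cross-hybridising probes, and its 3 transcript clusters rose by 1.23 to 1.40. AADACL4 passed the test but lay below the background cutoff in both groups, so its change has no reliable size.

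The measured difference of HAS2 was -4.91 ± 0.10 (limma adjusted p = 4.04e-08), and its transcript cluster lies on chromosome 8 at 122625538 to 122653630. Several other genes fell to below the cutoff, so that their folds are lower bounds. VSNL1, a neuronal calcium sensor, fell at least 4.14-fold and MID1IP1, a regulator of fatty acid synthesis, at least 2.73-fold. SLC8A1, a sodium-calcium exchanger, fell at least 2.98-fold and the nuclear receptor gene RORB at least 2.04-fold. IFI16, a sensor of foreign DNA, fell from 9.50 to 7.60 (adjusted p = 3.69e-07). The potassium channel gene KCNK2 fell at least 2.73-fold, DSEL on chromosome 18 at least 1.74-fold, CDH8 on chromosome 16, a cadherin gene, at least 2.73-fold and LRRN1 at least 1.91-fold. The lipase-family gene PNPLA4 fell by 1.84. ANXA1, an annexin that binds membranes in the presence of calcium, fell from 9.99 to 8.46. All 24 of these genes were past the threshold in the same direction under every alternative that kept them among the genes tested. The effect in overexpression differed from that in knockdown for 23 of them, with LY6G6D the exception (adjusted p of the difference = 0.404).

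**Figure D2:**
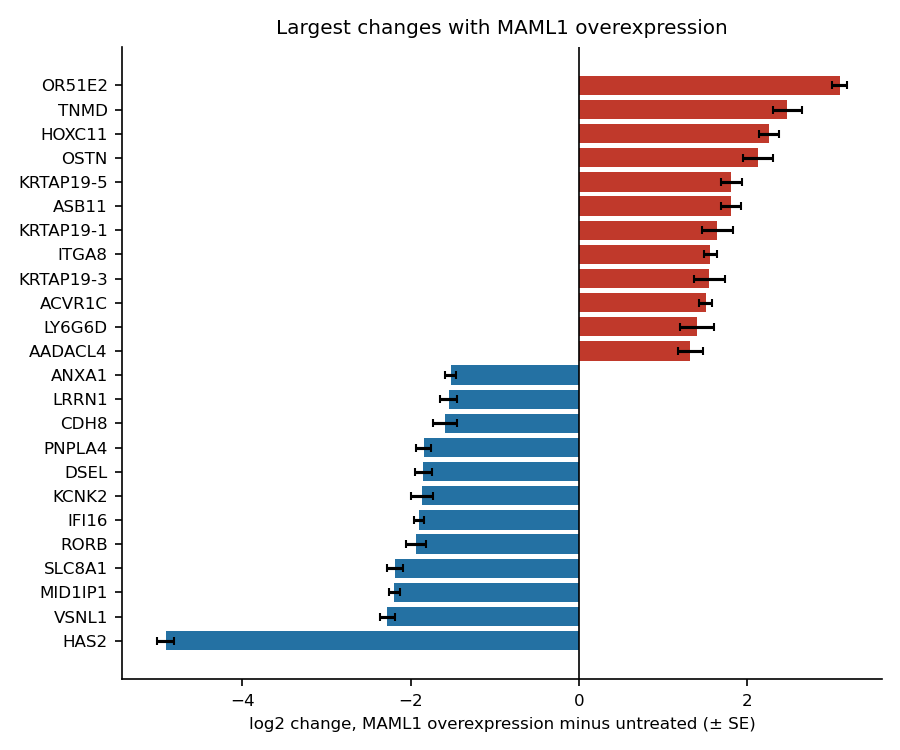
Log2 change with MAML1 overexpression (overexpressing minus untreated, 3 arrays each) of the 12 genes with the largest measured rise (red) and the 12 with the largest measured fall (blue); error bars are the SE. The bars are measured differences, from HAS2 (-4.91) to OR51E2 (3.10); 13 of the genes lie below log2 5 in 1 group and AADACL4 in both, where the size is uncertain.

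HOX genes, which pattern the body axis, rose in number: 12 of 38 rose, 3 fell and 23 did not pass (15 rose and 4 fell when adjusted over the list alone). Besides HOXC11, HOXD13 rose by 0.76 ± 0.06, HOXA6 by 0.57 ± 0.07 and HOXA9 by 0.45 ± 0.06. By cluster, 4 of 11 HOXA, 1 of 10 HOXB, 4 of 8 HOXC and 3 of 9 HOXD genes rose. The genes that fell were HOXA7 (-0.38), HOXB7 (-0.37) and HOXD8 (-0.45), which were chosen after their values were seen. The list rose against other genes with camera's preset correlation (adjusted p = 0.000231), but not with its own correlation (adjusted p = 0.678 with an estimated correlation).

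**Figure D3:**
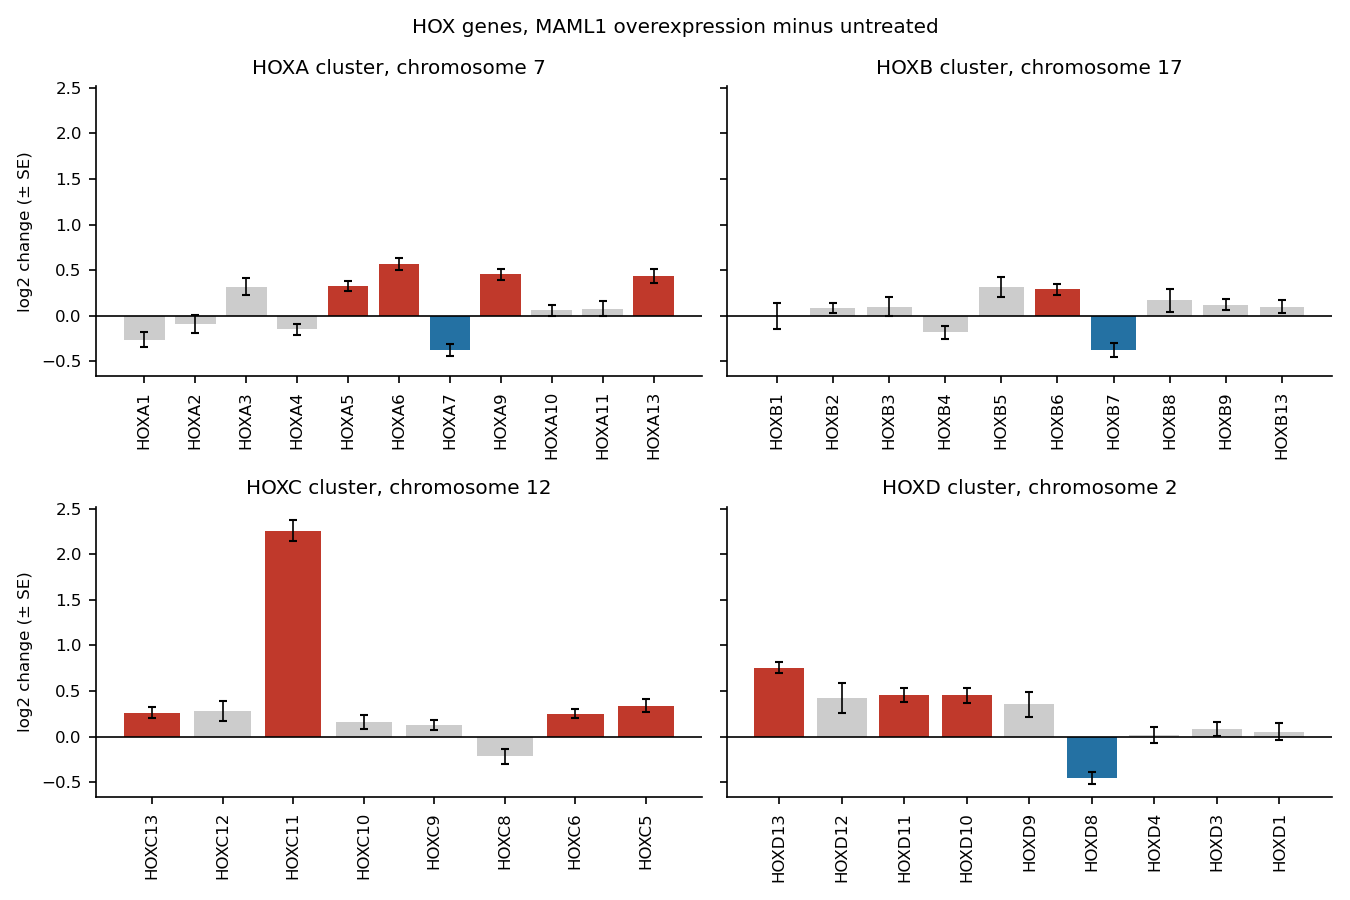
Log2 change of each HOX gene with MAML1 overexpression (overexpressing minus untreated, 3 arrays each), in order along the 4 clusters; bars are red where the gene rose, blue where it fell and grey where it did not pass an adjusted p of 0.05, and error bars are the SE. HOXC11 stands highest at 2.26.

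Among p53 target genes, CDKN1A, an inhibitor of cyclin-dependent kinases, fell (-0.69 ± 0.07). BTG2, which restrains proliferation (-0.49 ± 0.07), and MDM2, the ubiquitin ligase that limits p53 (-0.26 ± 0.06), fell too, and no other member did. Of 25 members, 0 rose, 3 fell and 22 did not pass (6 fell when adjusted over the list alone; camera adjusted p = 2.8e-05, adjusted p = 0.259 with an estimated correlation). Among mesenchymal genes, SPARC fell by 0.96, FN1 by 0.69, SNAI2 by 0.45 and VIM by 0.40. They encode the matrix proteins SPARC and fibronectin, a transcription factor and the filament protein vimentin. Of 27 mesenchymal members, 1 rose, 8 fell and 18 did not pass (1 and 9 when adjusted over the list alone; camera adjusted p = 0.000231, adjusted p = 0.259 with an estimated correlation). Of 53 extracellular matrix genes, 0 rose, 8 fell and 45 did not pass (1 and 11 when adjusted over the list alone; camera adjusted p = 0.0393, adjusted p = 0.815 with an estimated correlation). They included EFEMP1 (-0.94), VCAN (-0.60) and COL2A1 (-0.59). SPARC and FN1 are in the mesenchymal and the matrix list and were counted in both. The test and the mean (-0.10) of the matrix list were negative while its median was 0.02, and camera no longer called it after quantile normalisation (adjusted p = 0.0527), in a fit of the compared groups only (0.0694), without untreated replicate 2 (0.165) or overexpression replicate 1 (0.116), or without chromosomes 18, 20 and 16q (0.0586).

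Among 505 zinc finger genes of the ZNF series, 3 rose, 35 fell and 467 did not pass (6 and 39 when adjusted over the list alone; camera adjusted p = 0.00178, adjusted p = 0.772 with an estimated correlation). ZNF532 on chromosome 18 fell by 1.38 and ZNF717 by 1.24. Core histone genes fell in 5 of 61 cases with 0 rises, H3C11 by 1.41 and H3C7 by 1.09 (the same counts when adjusted over the list alone; camera adjusted p = 0.00927, adjusted p = 0.262 with an estimated correlation). Of 86 ribosomal protein genes, 1 fell, RPL26 (-0.38), and 0 rose (0 when adjusted over the list alone; camera adjusted p = 0.00927, adjusted p = 0.259 with an estimated correlation). Of 24 cholesterol synthesis genes, 1 fell, IDI1 (-0.41), and 0 rose (3 fell when adjusted over the list alone; camera adjusted p = 0.0393, adjusted p = 0.678 with an estimated correlation). After quantile normalisation camera called neither the ribosomal (adjusted p = 0.598) nor the cholesterol list (0.155). The cholesterol list was also not called in a fit of the compared groups only (0.0543), without untreated replicate 2 or 3 (0.101 and 0.0986) or without overexpression replicate 1 or 2 (0.116 and 0.0629). Of the 8 lists that camera called with overexpression, fry, which does not compare a list with other genes, called the HOX, p53, mesenchymal, histone and ribosomal lists (adjusted p = 0.00831 to 0.009998), but not the matrix (0.253), zinc finger (0.202) and cholesterol (0.0557) lists.

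The Notch lists did not pass camera. Of 39 Notch pathway genes, NUMB rose (0.23 ± 0.05) and DTX3 fell (to 4.35, below the cutoff), the same count as when adjusted over the list alone. Of 21 Notch target genes, 2 rose, 3 fell and 16 did not pass (3 and 3 when adjusted over the list alone). BMP2, a secreted growth factor, rose by 1.05 and the repressor gene HEYL by 0.48, while HEY1, a repressor of the same family, fell by 0.39. Of 29 genes of the DNA methylation machinery, CTCFL fell (-0.49) and 0 rose (2 fell when adjusted over the list alone), and of 20 clustered protocadherins, PCDHB2 rose (0.47) and 0 fell, with the same count when adjusted over the list alone. Developmental transcription factors went both ways, with 5 rises and 11 falls among 100 (10 and 15 when adjusted over the list alone), and SOX11 (-1.41), LHX1 (-1.35), PAX2 (-0.92) and LHX2 (-0.59) fell. Epithelial genes did so too, with 5 rises and 3 falls among 33 (7 and 6 when adjusted over the list alone). EPCAM (0.78) and the cadherin gene CDH3 (1.20) rose, and MAL2 (-1.40) and CLDN7 (-0.85) fell. CDH3 lies on 16q, where 36 of 41 changed genes rose. CTCFL lies on chromosome 20, where 82 of 85 changed genes fell.

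Markers of other cell types changed in small numbers and none of their lists passed camera. Of 33 neuronal genes, 2 rose and 3 fell, with the neurofilament genes NEFH (at least 1.43-fold, to below the cutoff) and NEFL (-0.66) lower and CNTN1 (0.85) higher. Of 29 kidney genes, LHX1 and PAX2 fell. Of 18 keratinocyte and HeLa-type genes, ANXA1, CAV1 (-0.31) and SFN (-0.33) fell and 0 rose. Of 12 endothelial genes FLT1 fell (-0.53), and of 18 blood cell genes LCP1 rose (0.44). None of 16 hepatocyte genes and none of 24 muscle and MEF2 genes passed. Adjusted over the list alone, 3 neuronal genes rose and 5 fell, and the counts of the other 6 lists stayed as given.

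**Figure D4:**
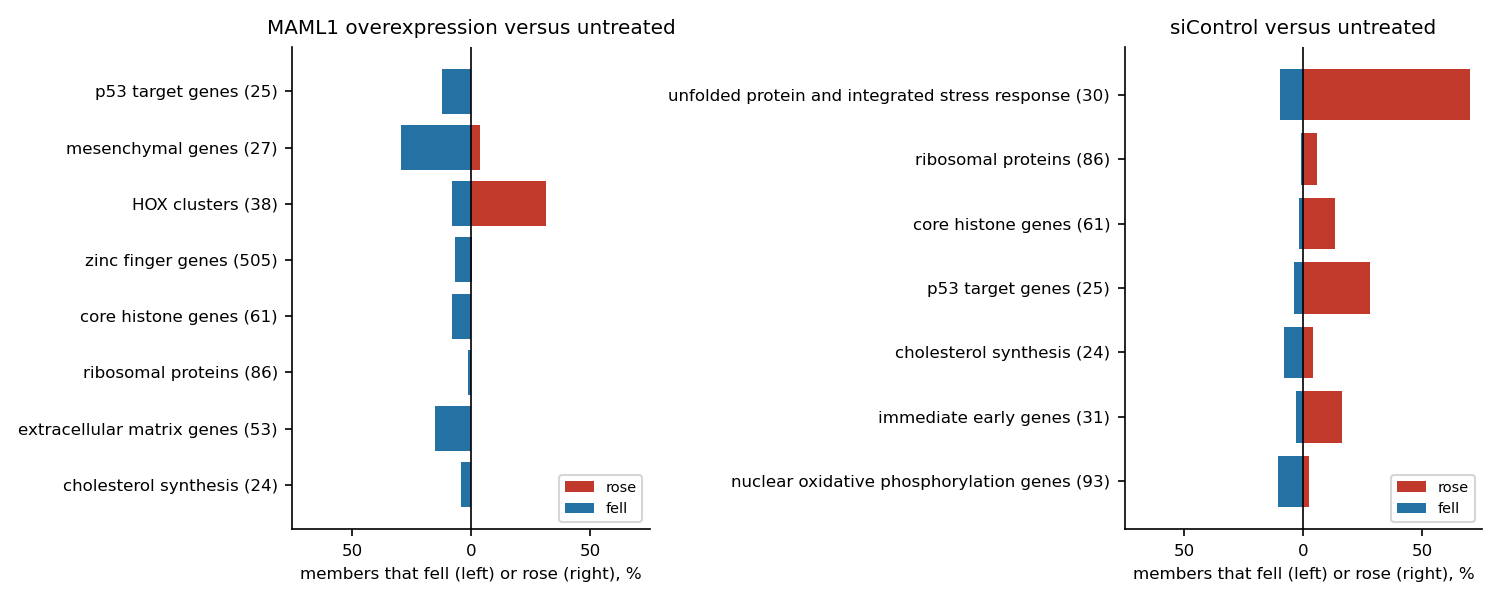
Percentage of the members of each gene list that rose (red, right) or fell (blue, left), for the lists past camera's preset-correlation test with overexpression and in siControl against untreated cells; the number of genes in each list is in parentheses. HOX genes have 12 rises in 38 with overexpression, and stress response genes have 21 rises in 30 in siControl cells.

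Of the genes tested, 5225 (25.7%, against 10% by chance) had no overlap between the 3 overexpressing and the 3 untreated arrays, and all 1024 changed genes were among them. At the filter of the series text, 263 genes passed, 101 up and 162 down, and 279 transcript clusters passed it in the authors' deposited table. The series text states 225 genes. An equal-variance test of each gene by itself gave 224, and of the 279 clusters, 262 had a group mean of at least log2 5 and held 223 genes. The count of 1024 fell to 511, 462 and 524 without untreated replicates 1, 2 and 3, and to 668, 630 and 575 without overexpression replicates 1, 2 and 3. Changed genes were unevenly placed on the chromosomes: 82 of the 85 on chromosome 20 and 32 of the 36 on chromosome 18 fell, and 36 of the 41 on 16q rose. Together these held 15.8% of the changed genes and 6.08% of all genes.

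**Figure D5:**
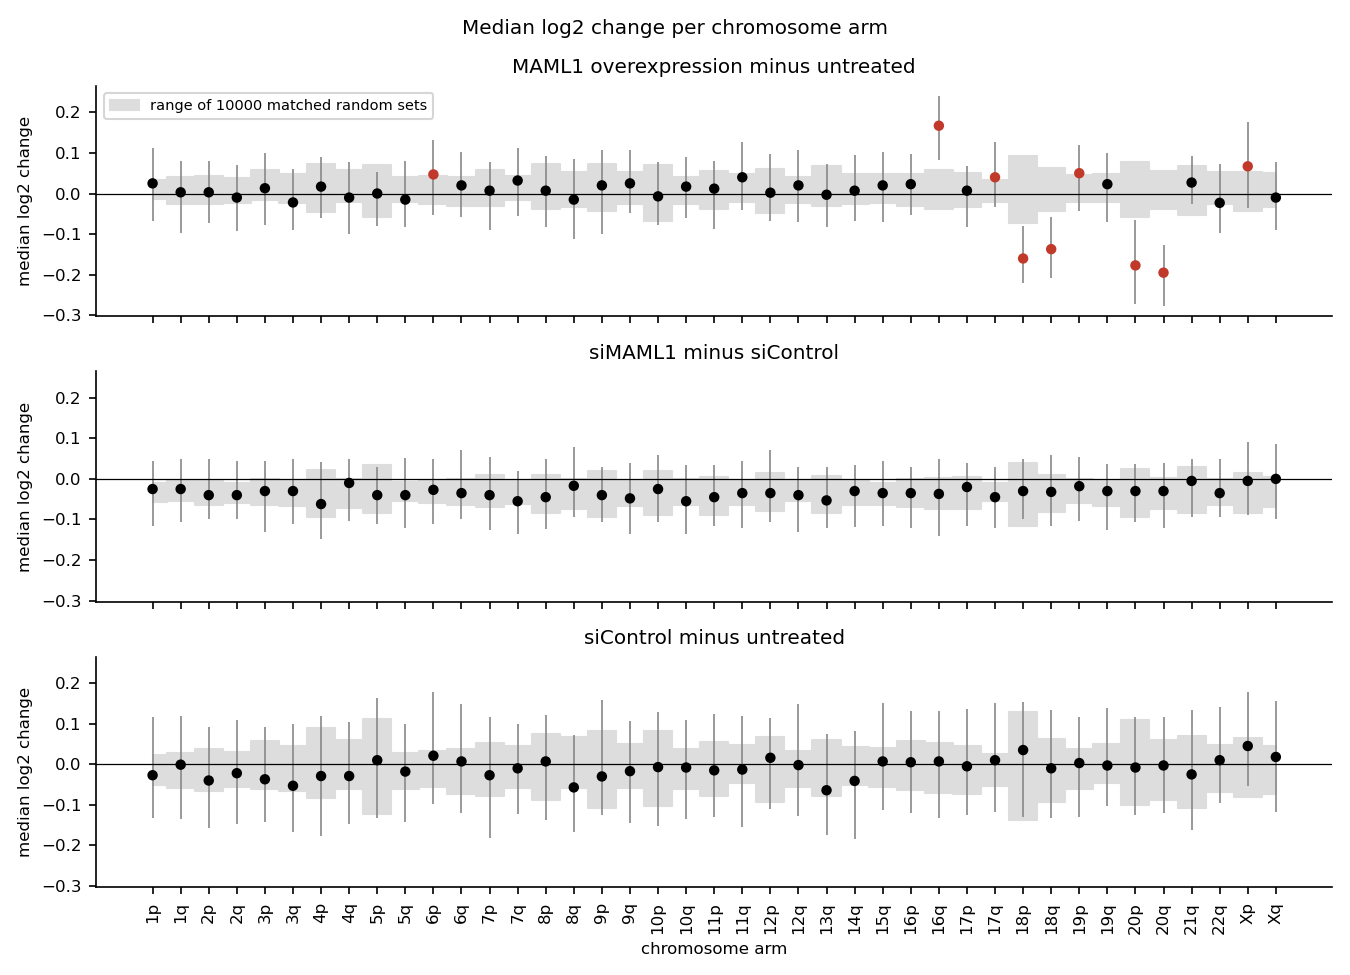
Median log2 change per chromosome arm of genes with a mean above log2 7, for overexpression, knockdown and siControl against untreated; lines are the interquartile range over genes, the grey band is the range of 10000 random gene sets matched on expression, and red points lie outside it. In overexpression 9 of 41 arms lie outside the band, and in the other 2 comparisons 0 do.

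The second comparison asked what lowered MAML1 does, with siMAML1 against siControl cells. No gene passed, so the values that follow are differences that limma did not call. Lying highest by p were WDFY1, an adapter on endosomes (0.66 ± 0.08), B4GALT6, a glycolipid enzyme (0.48 ± 0.06), EMP1 (0.59 ± 0.08), the kinase gene HIPK3 (0.51 ± 0.07), KCTD12 (0.45 ± 0.07) and CNN2 (0.54 ± 0.08). Lying lowest were the phosphatase gene INPP5D (-0.99 ± 0.12), the histone gene H2AC14 (-0.70 ± 0.09), CBS of sulphur amino acid metabolism (-0.50 ± 0.07), OXCT1 of ketone use (-0.66 ± 0.09), CRYBA4 (-0.48 ± 0.07) and the cystine transporter gene SLC7A11 (-0.75 ± 0.11). All 12 had a limma adjusted p of 0.0651, the smallest of the comparison, with 2 arrays in each group. H2AC14 and CRYBA4 lay below the background cutoff in both groups, and EMP1 in siControl cells. Of these 12, 11 lay in the opposite direction to their difference between siControl and untreated cells, but that comparison shares the siControl arrays. Simulated arrays without effects gave a mean of 11.4 (9 to 12). The simulated arrays lacked the siControl effects of the real ones, so 11.4 sets no bound.

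In knockdown, hypoxia and glycolysis genes lay higher as a list (median 0.18). ALDOC (0.70) and HK2 (0.50), enzymes of glycolysis, and EGLN3 (0.39), an oxygen sensor, were among them. Of its 30 members 0 passed, and 12 were higher when adjusted over the list alone (camera adjusted p = 1.65e-14, adjusted p = 0.316 with an estimated correlation). Of 24 cholesterol synthesis genes 0 passed, and 3 were higher when adjusted over the list alone, with MSMO1 at 0.45 and INSIG1 at 0.38 (camera adjusted p = 4.9e-06, adjusted p = 0.316 with an estimated correlation). Clustered protocadherins lay lower, with PCDHB2 at -0.44 (0 of 20 passed, also when adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.328 with an estimated correlation). The members PCDHGC5, PCDHB12 and PCDHB5 lay below the background cutoff in both groups, and the list was not tested without the dimmest 40% of genes. Dim genes lay lower on most arms: on 1p, the median was -0.105 for genes below log2 5 and -0.025 for genes above log2 7. A shift of this list was thus not told apart from that of dim genes.

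A further 6 lists lay higher by camera in knockdown with 0 members passed. They were immediate early genes (camera adjusted p = 4.57e-05, adjusted p = 0.393 with an estimated correlation), extracellular matrix genes (0.000289, and adjusted p = 0.555 with an estimated correlation) and oxidative phosphorylation genes (0.0015, and adjusted p = 0.316 with an estimated correlation). The others were developmental transcription factors (0.00236, and adjusted p = 0.555 with an estimated correlation), mesenchymal genes (0.00488, and adjusted p = 0.316 with an estimated correlation) and NF-kB target genes (0.04998, and adjusted p = 0.328 with an estimated correlation). Adjusted over the list alone, 1 immediate early gene was higher, 3 mesenchymal genes were higher and 1 lower, 3 NF-kB target genes were higher and 2 lower, and 0 passed in the other 3 lists. By fry none of these 6 lists passed (adjusted p = 0.313 to 0.747), nor did the hypoxia list (0.0674), while the cholesterol list lay higher and the protocadherin list lower (both 0.04994). Replication and mitosis genes lay lower by fry alone (0.0124), with a median of -0.07 where that of all genes was -0.06. The HOX list did not pass in knockdown (camera adjusted p = 0.936), with a median of -0.06 equal to that of all genes and a test in the upward direction. Camera called 5 lists without siMAML1 replicate 2, where those of immediate early (adjusted p = 0.0699), matrix (0.326), developmental transcription factor (0.345), protocadherin (0.0743) and NF-kB target genes (0.142) were lost and the mean of the matrix list was -0.04. Without siMAML1 replicate 1 the mesenchymal (0.0717), oxidative phosphorylation (0.192), protocadherin (0.0606) and NF-kB (0.0717) lists were lost. Without siControl replicate 2 the oxidative phosphorylation (0.123) and protocadherin (0.204) lists were lost, and without replicate 1 the NF-kB list (0.213). The NF-kB list was also lost with the mean over clusters (0.0565), without the dimmest 40% of genes (0.128), after centring (0.0578) and with array weights (0.0527), and the protocadherin list after quantile normalisation (0.0875).

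Limma called 0 genes between siMAML1 and siControl at an adjusted p of 0.05, while 2953 had an unadjusted p under 0.05. An equal-variance test of each gene by itself with Benjamini-Hochberg adjustment called 13. With 2 arrays a group and values rounded to 2 decimals, that test can take the spread of a gene as 0, so its count is not reliable. A limma fit without the dimmest 40% of genes called 162, one after quantile normalisation 35, and a trended robust fit 325, and 3 were called without siControl replicate 2. At the series filter 80 genes passed, 28 higher and 52 lower, against 158 without siControl replicate 1 and 268 without siMAML1 replicate 2, and 28 transcript clusters passed in the authors' deposited table.

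The genes moved by overexpression were then followed in knockdown, to ask whether they went the other way when MAML1 was lowered. The 156 genes that fell at least 1.5-fold with overexpression had a median of 0.03 in knockdown, with 94 higher and 61 lower (median -0.01 without siMAML1 replicate 2), where the median of all genes was -0.06. They lay higher than other genes with camera's preset correlation (adjusted p = 1.87e-08, adjusted p = 0.0718 with an estimated correlation), and fry gave an adjusted p of 0.263. The 98 genes that rose had a median of -0.03 in knockdown, with 46 higher and 51 lower, and of 0.05 without siMAML1 replicate 1 and 0.02 without siControl replicate 2. For these camera's direction was upward (adjusted p = 0.0468, adjusted p = 0.420 with an estimated correlation), opposite in sign to their median and mean, and the call was lost without siControl replicate 1 (p = 0.527) or siMAML1 replicate 2 (p = 0.327). The effects of overexpression and knockdown differed for 562 genes, with HAS2 (difference -5.29 ± 0.16), MID1IP1 (-2.41 ± 0.11), OR51E2 (3.32 ± 0.15) and IFI16 (-2.02 ± 0.09) at the smallest p. Of these 4, all but IFI16 had a group below the background cutoff, so the sizes of their differences are not settled. The 562 became 297, 240 and 321 without untreated replicates 1, 2 and 3, and 313 and 330 without overexpression replicates 1 and 3. Without siControl replicates 1 and 2 it was 189 and 226, and without siMAML1 replicate 1 it was 204.

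The third comparison, siControl against untreated cells, showed how the control arms differ. Genes of the unfolded protein and integrated stress response rose: CHAC1, which degrades glutathione, by 1.75 ± 0.15, SLC7A11, which imports cystine, by 1.41 ± 0.10, ASNS, which makes asparagine, by 1.19 ± 0.08, and SLC7A5, an amino acid transporter, by 0.74 ± 0.07. Of 30 members of this list 21 rose, 3 fell and 6 did not pass (24 and 4 when adjusted over the list alone; camera adjusted p = 1.77e-10, adjusted p = 0.124 with an estimated correlation). Among the largest rises were the stress gene NUPR1 (1.83 ± 0.18), CHAC1, the collagen receptor gene DDR2 (1.70 ± 0.13), INPP5D (1.52 ± 0.11) and PCK2 (1.49 ± 0.13) of mitochondrial gluconeogenesis. The largest falls were ETV1 (-1.43 ± 0.10), an ETS transcription factor, NTS (-1.02 ± 0.12), which encodes neurotensin, SLC35G1 (-1.01 ± 0.08), POP1 (-0.90 ± 0.15), MAP1A (-0.90 ± 0.14) and SLC43A2 (-0.87 ± 0.15). Without siControl replicate 2 the last 3 had adjusted p-values of 0.0638, 0.055 and 0.0877, and POP1 also missed the threshold without replicate 1 (0.0542).

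Among p53 target genes in siControl cells, 7 of 25 rose and 1 fell (9 and 1 when adjusted over the list alone; camera adjusted p = 0.00574, adjusted p = 0.506 with an estimated correlation). SESN2 (0.82), DDB2 (0.63) and GADD45A (0.59) rose and TIGAR fell (-0.74). Of 31 immediate early genes, 5 rose, 1 fell and 25 did not pass (12 and 1 when adjusted over the list alone; camera adjusted p = 0.0278, adjusted p = 0.930 with an estimated correlation). FOSB (at least 2.31-fold, from just below the cutoff), FOS (1.14) and KLF10 (0.80) rose, and DUSP6, which restrains ERK signalling, fell (-0.77). Of 61 core histone genes, 8 rose and 1 fell, the same counts as when adjusted over the list alone, with H4C14 at 0.99 (camera adjusted p = 0.00574, adjusted p = 0.256 with an estimated correlation). Of 86 ribosomal protein genes, 5 rose and 1 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.00136, adjusted p = 0.124 with an estimated correlation), and the probe sets of the member that fell, RPL27A, differed in sign.

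Of 93 oxidative phosphorylation genes in siControl cells, 2 rose and 10 fell, the same counts as when adjusted over the list alone, with NDUFB6 at -0.37 (camera adjusted p = 0.0351, adjusted p = 0.506 with an estimated correlation). Of 24 cholesterol synthesis genes, 1 rose and 2 fell, ACAT2 (-0.60) and NSDHL (-0.50) (1 and 4 when adjusted over the list alone; camera adjusted p = 0.0204, adjusted p = 0.506 with an estimated correlation). After quantile normalisation camera called neither of these lists (adjusted p = 0.471 and 0.151). Camera called 7 lists in all, and 4 without siControl replicate 2, where the oxidative phosphorylation (adjusted p = 0.276), cholesterol (0.0529) and immediate early (0.262) lists were lost. Without the dimmest 40% of genes the immediate early and cholesterol lists (both 0.1004) and the oxidative phosphorylation list (0.130) were lost. The last was also lost without untreated replicate 1 (0.130), with the mean over clusters (0.0564), with array weights (0.0506), in a fit of the compared groups only (0.0557) and without chromosomes 18, 20 and 16q (0.0522). Of the 7 lists, fry called all (adjusted p = 0.000212 to 0.0460) but that of immediate early genes (0.116). It also called the 21 Notch target genes higher (0.0173), of which 5 rose and 2 fell (6 and 3 when adjusted over the list alone; camera adjusted p = 0.177, adjusted p = 0.892 with an estimated correlation). Of 38 HOX genes 5 fell and 0 rose, the same counts as when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.168).

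In siControl against untreated cells 2214 genes changed, 1177 up and 1037 down, and with each array centred on its median the split was 826 up and 1214 down. At least 1.5-fold were 297, of which 215 rose and 82 fell. The groups did not overlap for 9079 genes (44.7%, against 20% by chance). The count of 2214 was 1128, 1171 and 1364 without untreated replicates 1, 2 and 3, and 1005 and 340 without siControl replicates 1 and 2.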

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

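No test of an explanation was run on the results in this part, which concern features outside the set of named genes; they were picked because a signal appeared in data that the comparisons above did not use. Transcript clusters with no gene symbol changed with MAML1 overexpression in 41 of 4519 cases (0.907%), 13 up and 28 down, against 587 of 22371 named clusters (2.62%) in the same limma fit. Control features placed in introns changed with overexpression in 12 of 2904 cases (0.413%). Between siControl and untreated cells 30 intron control features changed (1.03%). On siMAML1 replicate 1, 24 intron control features lay over 2 log2 units above their own median, against 0 to 7 on each of the other 9 arrays, while the median of all intron control features on that array was 4.79, within the range of 4.74 to 5.08 over the arrays. That array also had the largest spread of deviations from each gene's median over all arrays (interquartile range 0.22, against 0.13 to 0.21).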

How the results depend on the processing

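The t-test on linear values, the fit without siMAML1 replicate 1 for the comparisons that do not involve it, the fits without chromosomes 18, 20 and 16q, and the filter with a group mean of at least log2 5 were chosen after the data were seen. Leaving out the dimmest 40% of genes gave 1736 changed genes for overexpression, 162 for knockdown, 3390 for siControl against untreated and 1206 for the difference of effects, with fewer genes tested, and 37 knockdown genes at the series filter. A trended robust fit gave 1994, 325, 3519 and 1408, and quantile normalisation gave 35 genes in knockdown and 5 lists with overexpression; the cause was not tested. With at least 1.5-fold required, 254 genes remained for overexpression and 297 for siControl against untreated. At the series filter, knockdown had 0 genes with an adjusted p below 0.01, 7 by a plain t-test on log2 values and 6 on linear values, which do not pool the spread over genes. With an estimated correlation camera called 0 lists in overexpression, 0 in knockdown and 0 in siControl against untreated. Genes that rose with overexpression had a knockdown median of -0.0325 with an estimated correlation (p = 0.420) and in a fit of the compared groups only (p = 0.0519). That median turned to 0.03 without dim genes, 0.0125 after centring and 0.0502 after quantile normalisation, with p from 0.0578 to 0.1265. These settings move the median of all genes, which was -0.06 in knockdown and -0.02 after centring. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.005, 0.006 and -0.048 between untreated and overexpressing arrays and -0.077 between the siRNA groups. With the replicate block, 749 genes changed with overexpression, 0 in knockdown, 1418 in siControl against untreated and 292 in the difference of effects, and camera lost the cholesterol list in siControl against untreated (adjusted p = 0.0516).

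Leaving out 1 array at a time gave 462 to 1013 changed genes for overexpression (263 to 285 at the series filter), 0 to 3 for knockdown (80 to 268), 340 to 2125 for siControl against untreated and 189 to 566 for the difference. The upper ends of 1013 for overexpression and 2125 for siControl against untreated came from leaving out siMAML1 replicate 1, which is in neither comparison. Leaving out an array of the compared groups gave at most 668 changed genes for overexpression and 1364 for siControl against untreated. Where leaving out an array left 1 in a group, the remaining array was assumed to vary like the others. The knockdown median ran from -0.04 to 0.045 for genes that rose with overexpression and from -0.005 to 0.0975 for genes that fell, and for the former camera's call was lost without siControl replicate 1 or siMAML1 replicate 2. The MAML1 change ran from 0.508 to 0.618 with overexpression and from -0.75 to -0.29 in knockdown. Lists called numbered 6 to 10, 5 to 9 and 4 to 8 in the 3 comparisons. Of the 1024 genes, 880 were also called without dim genes, 995 in the trended fit, 960 after quantile normalisation, 873 after centring and 707 with the block. The second deposited table had the same values and so tests nothing. Over the alternatives, the 24 largest changes with overexpression kept their call in all 394 cases and the siControl genes in 187 of 191, and 30 of 164 knockdown values came under the threshold. Called lists were lost in 20 of 144 cases for overexpression, 26 of 134 for knockdown and 21 of 119 for siControl. All these cases include the second table, which could not change a call. The list cases also include the trended robust fit, which camera does not use, so that setting could not lose a list. Signal limits the dim genes: 30.1% of genes, and 5.47% of those changed with overexpression, had a mean below the background cutoff of log2 5.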

Other observations

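The 4 tests of the chromosome-wide shifts and the tests of neighbouring genes with the same symbol stem, shared probes included, were chosen after the results were seen, and the other tests of patterns before. Several further gene groups changed in part with MAML1 overexpression, with none of their lists past camera. The amino acid transporter genes SLC7A5 (0.42) and SLC3A2 (0.29) and ASNS (0.33) rose among 30 stress response genes, with 0 falls (5 rose and 2 fell when adjusted over the list alone). Among 25 TGF-beta and BMP target genes, INHBA (at least 1.79-fold, from below the background cutoff), a subunit of activin, NOG (0.63), an antagonist of BMPs, and CCN2 (0.45) rose and 2 fell, TGFB2 (-0.46) among them (3 and 3 when adjusted over the list alone). Among 31 immediate early genes 3 rose and 3 fell, with the ERK phosphatase genes DUSP5 (-0.79) and DUSP4 (-0.55) lower and CCN1 (0.49) and NR4A1 (0.49) higher (5 and 5 when adjusted over the list alone).

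Of 38 interferon response genes, IFI35 (0.35) and the RNA sensor gene IFIH1 (0.54) rose and SP100 fell, below the background cutoff in both groups (4 and 3 when adjusted over the list alone). The Wnt target genes CDX2 (0.43), CD44 (0.52) and RNF43 (0.31) rose and 1 of the 24 fell, SP5, whose probe sets differ in sign (4 and 3 when adjusted over the list alone). Of 38 replication and mitosis genes, the licensing factor gene CDT1 on 16q rose (0.46) and 3 fell, including E2F1 (-0.32) and UBE2C (-0.30) on chromosome 20 (1 and 6 when adjusted over the list alone). CCL2 fell (-0.64) and BIRC3 rose (at least 1.21-fold, from below the cutoff) among 23 NF-kB target genes, with the same count when adjusted over the list alone. PRDM14, below the cutoff in both groups, rose among 20 pluripotency genes (1 rose and 1 fell when adjusted over the list alone), and NDRG1 (0.46) among 30 hypoxia and glycolysis genes (1 and 1). RING1 (0.28) rose among 33 genes for histone acetyltransferases and Polycomb proteins, and NDUFB6 (-0.26) and, on chromosome 20, NDUFAF5 (-0.36) fell among 93 oxidative phosphorylation genes, but 0 passed in either list when adjusted over the list alone. CTCFL, on chromosome 20 and also in the DNA methylation list, alone changed among 32 cancer-testis genes, and 0 of 24 imprinted genes passed. Both counts were the same when adjusted over the list alone. Of 13 RNA interference genes 0 passed (1 rose when adjusted over the list alone).

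Expressed genes of whole chromosome arms were shifted in the overexpressing cells, with medians of -0.19 for 271 genes of chromosome 20, -0.14 for 169 of chromosome 18 and 0.17 for 202 of 16q. Against a bias that follows intensity, 9 of 41 arms lay outside all 10000 sets matched on expression (16q, 17q, 18p, 18q, 19p, 20p, 20q, 6p and Xp), and against a single array, the chromosome 20 median lay between -0.22 and -0.17 in all 9 pairs of arrays. Of the expressed chromosome 20 genes 92.2% were lower, which any chromosome-wide cause would give. A copy number difference, MAML1 acting on these chromosomes and selection of clones cannot be told apart, since no DNA and no empty-vector clones were measured and knockdown, with a chromosome 20 median of -0.03, called no gene. Without chromosomes 18, 20 and 16q, 795 genes changed and 238 passed the series filter.

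Knockdown differences ran opposite to those between siControl and untreated cells: 1533 of the 2214 genes changed in siControl cells had the other sign, and the covariance over genes was -0.0133 (correlation -0.373). The comparisons share the siControl arrays. Simulated arrays without effects gave a covariance of -0.00916 (-0.00992 to -0.00855), a correlation of -0.547 and 1943 of 2214 genes. Real siControl effects, which the simulated arrays lack, would dilute the correlation and the count. Neither therefore bounds what shared arrays give in the data. The covariance of the data lay outside the simulated range. With a different siControl array in each comparison, the 4 covariances ran from -0.00901 to -0.00156, all below the simulated -0.00101 to 0.00102. But the simulation drew each gene independently, and with siMAML1 replicate 1 a swap of the siControl arrays moved the covariance from -0.00156 to -0.00901. Both simulated ranges may thus be too narrow for real arrays, so shared arrays as the whole cause were not decided. With siMAML1 replicate 2 alone the mean covariance was -0.0041, so the negative sign did not rest on siMAML1 replicate 1, but the same limit applies. A smaller response to transfection in the siMAML1 cells may contribute (slope -0.098, and -0.197 to -0.026 by the siControl array used), but this and an effect of lowered MAML1 on the same genes cannot be told apart with 2 arrays a group.

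Neighbouring genes changed the same way with overexpression in 61 pairs, against a mean of 38.4 in shuffles within arm and expression (5 of 10000 as high). Without chromosomes 18, 20 and 16q there were 37 against 20.3 (2 of 10000). Few shuffles reached either count, but the bar set beforehand, a count above all 10000 shuffles, was not met. Both counts lay within the range of the shuffles (highest 65 and 38), the outcome set beforehand for chance position and for the chromosome-wide shifts. Neither was thus excluded for all pairs together, and with so few shuffles as high, neither was shown. Pairs whose symbols share a stem numbered 18 against 2.50 (highest shuffle 11), and 16 against 1.70 (highest 9) without those chromosomes, which counts against chance position and the chromosome-wide shifts as the whole cause for these pairs. Pairs with different stems numbered 43 against 35.9, with 1182 of 10000 shuffles as high. No excess over chance position was thus detected for these pairs. Of the 18 pairs with the same stem, 16 hold no gene with cross-hybridising probes in the deposited annotation, which counts against shared probes as the whole cause, and 2 HLA pairs do hold them. Joint regulation of gene families was not tested and stays open.

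The 6 untreated and overexpressing arrays can be parted in 10 ways, too few for a share under 0.05. The real parting gave 1024 changed genes, 263 at the series filter and 8 lists, and the highest of the others gave 0, 6 and 6, so 1, 1 and 1 of the 10 partings reached the real counts. Each of the others put untreated and overexpressing arrays together in each group, so any real difference added to the spread there. Their counts are therefore no measure of what arrays without effects would give.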
